A study of Homo sapiens with 10 samples.

How the data were processed

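Total RNA from Hs 294T cells was labelled with biotin as cRNA from 4 ug per array and hybridised to Affymetrix arrays, per the labels. Cells were plated 3 h before treatment. The 10 arrays comprised 2 each of untreated cells at 0 h and of cells after 6 h in 0.01% DMSO, 100 nM elesclomol, 250 nM paclitaxel or both drugs. The labels call the arrays of a group technical replicates. The deposited value table holds intensity values for 54675 probe sets, which the authors made with MAS5 per the submitters' processing notes; the version and any scaling target are not stated. The values are linear signals with 1 decimal. The deposited lists of upregulated genes hold, per the authors' criteria, genes with a mean intensity of 500 or more (high list) or 50 to 500 (low list) in elesclomol, a fold of at least 1.5 over DMSO and an SE under 0.4. The authors' fold lay within a few percent of the ratio of the group means of the deposited signals, and its exact formula is not stated. The listed SD over the listed mean reached 0.4 at most. The lists also give, per the authors, the mean and SD of the elesclomol signals. Arrays give no counts, so no depth is stated.

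The following choices were made before the data were examined: the groups and comparisons, the test, the pseudocount and filter rules, the thresholds, the gene lists, the rule for named genes and most alternatives. Signals were read as log2(signal + 0.8), where 0.8 is the 10th percentile of all values. Probe sets with a mean signal of at least 9 (the median of all values) over the 10 arrays were kept and the 62 control probe sets left out, which gave 26589. A model with 1 mean per group was fitted over all 10 arrays in limma 3.58.1 (R 4.3.3), with 5 residual degrees of freedom, a moderated two-sided test with a trend in intensity, and Benjamini-Hochberg adjustment. No detection calls were used. Where a group mean lay under 9, each array of that group under 9 was taken as 9 in folds given as bounds. This rule was added after seeing the data. A probe set was called at an adjusted p under 0.05 and a fold of at least 2. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used for joining and drawing.

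The fit departed from the plan in scaling, and counts without scaling are given beside those reported. The plan took MAS5 signals as already scaled. The trimmed means (27.6 to 49.85) and the bacterial hybridisation controls differed between arrays of the same group, so quantile normalization, listed beforehand as another setting, was used instead. This was decided from the brightness of the arrays before any comparison was tested. Scaling to a common trimmed mean (2% off each tail) and to the hybridisation controls were alternatives chosen after seeing the data. Without scaling, the median log2 change of all probe sets was 0.25 in the combination against DMSO, 0.24 against paclitaxel and 0.21 against elesclomol, and 0.34 in DMSO against untreated cells. With the hybridisation controls these were 0.12, 0.11, 0.25 and 0.50, and elesclomol had -0.13 against DMSO and -0.14 against paclitaxel. The interaction had 0.205 without scaling and 0.245 with those controls. With a common trimmed mean no median passed 0.1 in size. All changes are relative to the median after quantile normalization, so a change shared by all transcripts would not be seen.

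No annotation of the probe sets was used here, so counts are of probe sets, where the plan had 1 probe set per gene. The authors' lists give gene names without probe sets. Each listed gene was matched to the probe set whose elesclomol mean and SD agreed within 0.1 signal units and whose fold agreed within 5% and rounding. This matched 1603 of 1614 entries to 1 probe set; with the SD values shuffled, 0.75% of the high list and 0.52% of the low list matched. Symbols were updated through the gene table of GRCh38.p14, used for names only: of the listed symbols 818 were current, 181 were updated through a synonym and 58 were kept as listed. Tested probe sets with a single symbol numbered 1449, for 1056 genes, each represented by its probe set with the highest mean signal. The authors selected the named genes for a high elesclomol signal against the same DMSO arrays. Elesclomol against DMSO is therefore not independent evidence for them. By this selection paclitaxel against DMSO, the combination against DMSO and elesclomol against paclitaxel are biased upward. The combination against elesclomol, the interaction and DMSO against untreated cells are biased downward. The combination against paclitaxel uses other arrays. The fits with 1 probe set per gene over all genes, and with the mean over the probe sets of a gene, need that annotation and were not run.

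Named genes were the 12 largest rises and 8 largest falls in elesclomol and in the combination against DMSO, and the 6 largest each way elsewhere, among calls with every array of the 2 groups apart. To these were added, for each list called or with 3 or more called members, the 4 largest changes and up to 2 members that did not pass, and 16 genes always reported. Of those 16, 9 could be named. HMOX1, TUBB, TUBB2A, TUBA1B, CCNB1, FDX1 and MITF had no named probe set, so their changes are not known here. No fall could be named.

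Of 25 gene lists fixed in advance, 14 had at least 3 named genes tested. They were tested within the 1056 named genes with camera (preset correlation 0.01), adjusted over the 14 lists of each comparison. Camera with an estimated correlation, camera on ranks, fry, and the lists set against all probe sets were alternatives, the last chosen after seeing the data. The 11 lists too small to test were described by members. SLBP (G1/S and replication genes) had 0.67, SDHD (oxidative phosphorylation) 0.46, ISCA1 0.94 (iron-sulfur and lipoylation genes), and FTL (iron homeostasis) 0.46 in elesclomol against DMSO, none called. Of the ribosomal proteins RPL37 was called at 1.35. Some members of these lists are not reported here. G2/M and mitosis genes, tubulins, melanocyte lineage, and fibroblast, leukocyte and keratinocyte markers had no named member.

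The steps were tested on simulated data built on 26589 probe sets, with 50 changed probe sets drawn for each size of change. The shares called are therefore imprecise. For elesclomol against DMSO, 52% of probe sets given a change of log2 1.25 were called, 36% at 1.5, 62% at 2 and 82% at 3, with 1 false call. For the combination against paclitaxel the shares were 60%, 42%, 66% and 84%, with 2 false calls. For the interaction they were 24%, 24%, 46% and 74%, with 4 false calls. A heat shock list shifted by 0.25 in the combination against paclitaxel was called in 20 of 20 draws, and with no shift in 0 of 20. The simulated probe sets varied independently and no gene outside the list changed, so this does not test list calls among correlated genes. The alternatives covered pseudocount, filter, scaling, thresholds, spread model, arrays in the fit, the replicate number as a block, and each array left out in turn, where the remaining array of a group was assumed to vary like the other groups.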

Results

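Gene expression was measured in Hs 294T, an established human melanoma cell line, 6 h after exposure to elesclomol, paclitaxel or both. Elesclomol is a small molecule that carries copper into cells, and paclitaxel is a drug that stabilises microtubules. The 10 arrays fell into 5 groups of 2: untreated cells at 0 h, and cells after 6 h in 0.01% DMSO, 100 nM elesclomol, 250 nM paclitaxel, or 100 nM elesclomol with 250 nM paclitaxel (the combination). The labels call the 2 arrays of each group technical replicates, so every SD, SE and p-value below measures the spread between arrays and not between cultures. The trimmed mean of the deposited signals ran from 27.6 on the second untreated array to 49.85 on the second combination array, and the number of arrays limits the precision of every value. After filtering, 26589 probe sets were tested, and 1056 genes could be named. Names came only from the authors' lists of genes raised by elesclomol, so no gene that fell could be named.

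The comparison of elesclomol with DMSO asked what elesclomol alone changed. Of the genes tested, 16 of 27 heat shock chaperones, 5 of 7 metallothioneins, 6 of 13 NRF2 antioxidant genes and 6 of 13 integrated stress response genes rose after elesclomol. Only members named through the authors' lists were tested, out of 30, 12, 30 and 24 genes in these lists. Of all 1056 named genes 210 were called higher. The NRF2 and integrated stress response lists lost their call with an estimated correlation (adjusted p = 0.168 and adjusted p = 0.0937). HSPA6, a strictly stress-inducible HSP70 family member, had a deposited signal of 8.65 ± 0.778 (SD, n = 2) in DMSO and 3657 ± 435 (SD, n = 2) after elesclomol. Signals under 9, the median of all values, were not shown to lie above background and were set to 9 for folds given as bounds; HSPA6 rose at least 338-fold after scaling. In the untreated cells HSPA6 had a signal of 3.3 ± 1.98 (SD, n = 2). ZFAND2A, an arsenite-inducible zinc finger gene, went from 192.7 ± 47.9 to 3533 ± 266 (SD, n = 2 each) and rose 16.6-fold.

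Of the 27 heat shock chaperone genes tested, 16 rose after elesclomol and 11 did not reach the 2-fold limit; the count adjusted over the list alone was also 16. HSPA1B rose by 3.60 ± 0.104 on the log2 scale, and DNAJB1, an HSP40 co-chaperone, by 2.79 ± 0.064. DNAJB4 rose by 2.77. HSPA1A rose by 1.35, although its near-identical copy HSPA1B leaves uncertain how the signal divides between the pair, and HSPA6 also has a close relative. The members below the limit included AHSA1 at 0.94 and HSPE1 at 0.84. Set against the other named genes with camera (limma), the list had an adjusted p = 2.68e-15, and an adjusted p = 0.00328 with an estimated correlation.

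Among metallothioneins, which bind copper and zinc, 5 of 7 rose, also 5 adjusted over the list alone. MT1F rose by 1.76, MT1H by 1.71, MT1G by 1.61 and MT1E by 1.56, all on the log2 scale, while MT2A at 0.62 stayed under the 2-fold limit. MT1X had 0.68 in its brightest probe set and passed with 1.73 in its other one. These probe sets can share signal between near-identical metallothionein genes, so the member is uncertain. The metallothionein list had an adjusted p = 1.19e-06 in camera and an adjusted p = 0.0203 with an estimated correlation. SLC30A1, the zinc exporter of the plasma membrane, rose by 2.19 ± 0.159. The other members of the copper and zinc handling list lay between 0.57 and 1.02. Of its 5 tested members 2 were called, SLC30A1 and the one at 1.02. The one at 1.02 lost its call without the first DMSO or the second elesclomol array. That list was not called in camera (adjusted p = 0.703).

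NRF2 antioxidant genes rose in 6 of 13 cases, also 6 adjusted over the list alone. SLC7A11, the cystine transporter, rose by 2.65 and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 2.46. TXNRD1 rose by 1.33 and SRXN1 by 1.33, while NFE2L2 at 0.66 and SQSTM1 at 0.63 stayed under the limit. The NRF2 list had an adjusted p = 0.0492, and an adjusted p = 0.168 with an estimated correlation. Of 13 integrated stress response genes, 6 rose, also 6 adjusted over the list alone. SESN2 rose by 2.75, ATF3 by 1.99, TRIB3 by 1.63 and DDIT3 by 1.32, while DDIT4 had 0.85 and SLC3A2 had 0.70. That list had an adjusted p = 0.00712, and an adjusted p = 0.0937 with an estimated correlation.

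Immediate early genes rose in 5 of 8 cases, also 5 adjusted over the list alone (adjusted p = 0.0492 for the list; adjusted p = 0.155 with an estimated correlation). IER5 rose by 2.57, DUSP1 by 1.79 and NR4A1 by 1.63, and EGR1 had 0.97. Among the 4 p53 targets tested, SESN2, which is also in the integrated stress response list, had the largest rise. CDKN1A had 0.44, under the limit. PMAIP1 had 1.04, which became 0.96 without the first elesclomol array. GADD45A had 1.01, which became 0.94 without the first DMSO array and 0.95 without the first elesclomol array. The p53 list had an adjusted p = 0.0476, and an adjusted p = 0.155 with an estimated correlation. Of the ER chaperone list, 3 of 12 rose (HERPUD1 by 1.55, DNAJB9 by 1.42 and XBP1 by 1.29) and HSPA5, the main ER chaperone, had 0.53; the list was not called (adjusted p = 0.296). The 7 proteasome subunits tested had a median of 0.76, and 1 of them, PSMD7 at 1.01, passed the limit. The ER chaperone and proteasome counts lie near the 210 of 1056 called higher over all named genes. PSMD7 had 0.81 without the first DMSO array, 0.96 without the second elesclomol array, 0.90 with a common trimmed mean, 0.85 with the hybridisation controls and 0.94 with 4 times the pseudocount. The proteasome list had an adjusted p = 0.0492, an adjusted p = 0.155 with an estimated correlation, and an adjusted p = 0.707 on unscaled signals.

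The apoptosis list (adjusted p = 0.963), the NF-kB and cytokine list (0.808), hypoxia and glycolysis genes (0.513), cholesterol synthesis (0.808) and short-lived mRNAs (0.808) were not called in elesclomol against DMSO. For the last 3 the test pointed down relative to the other named genes, although their medians were 0.70, 0.56 and 0.42. Among named genes in none of these lists, DUSP2, a phosphatase of MAP kinases, went from a signal of 6.1 ± 6.79 to 81.55 ± 16.2 (SD, n = 2 each), a rise of at least 7.68-fold. ARC rose at least 7.97-fold, and on the log2 scale EID3 rose by 2.95 and MXD1, a partner of MAX, by 2.49.

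**Figure D1:**
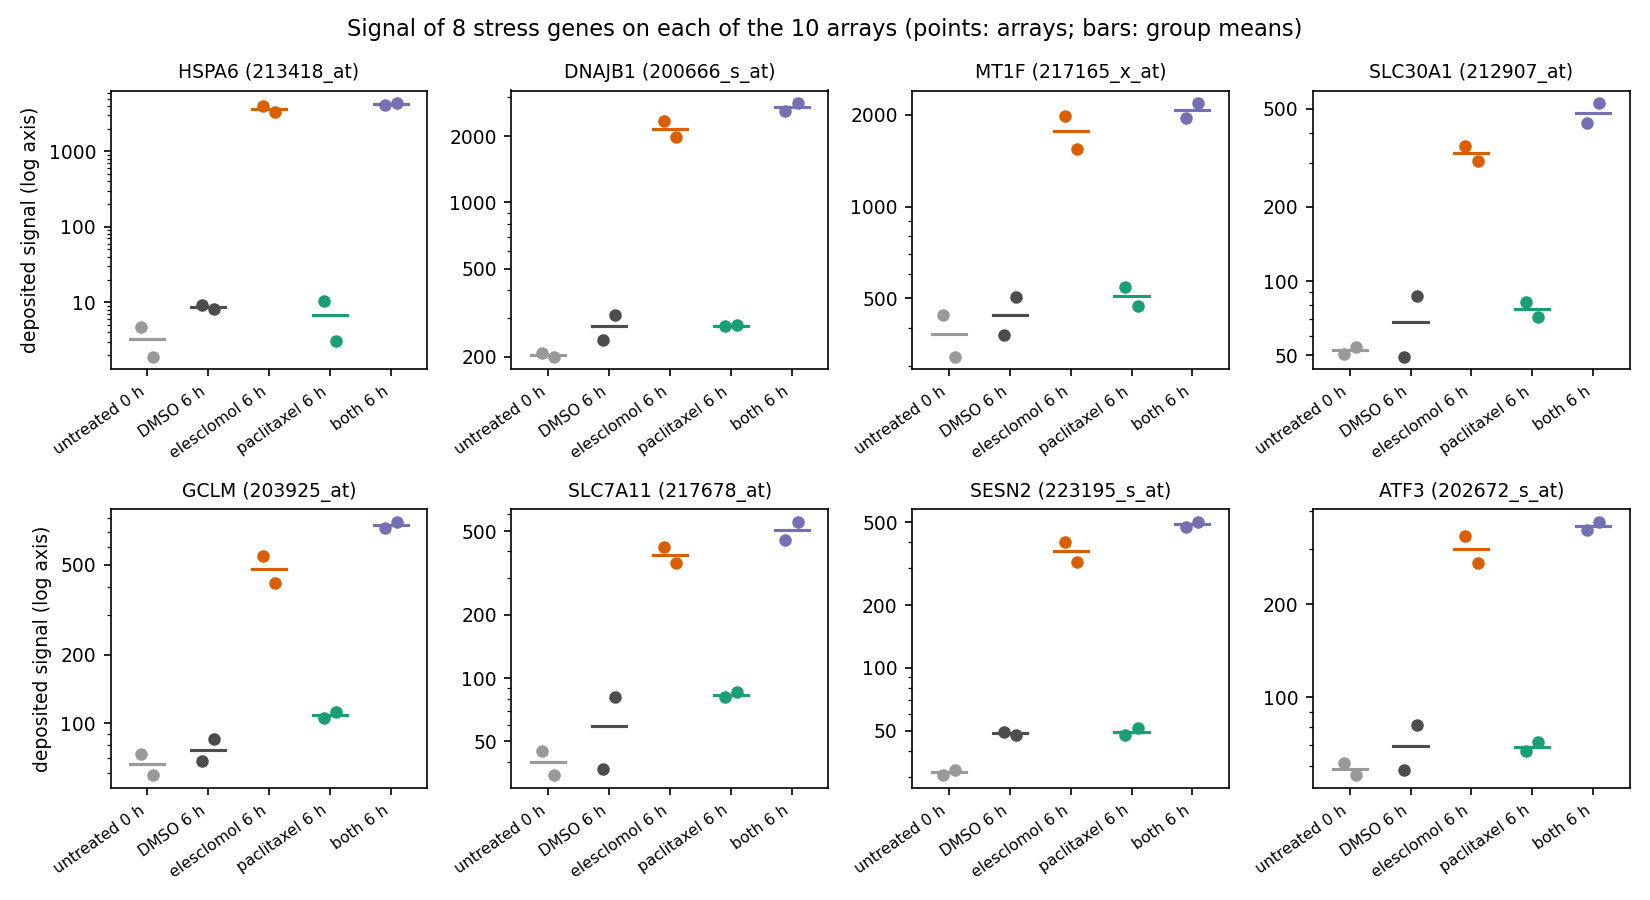
Deposited signal (log axis) of 8 stress genes on each of the 10 arrays; points are arrays and bars are group means (n = 2). Both groups with elesclomol lie above the DMSO, paclitaxel and untreated groups for each gene, with HSPA6 at 3657 after elesclomol and 8.65 in DMSO.

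Over all probe sets, limma called 1119 in elesclomol against DMSO, 692 higher and 427 lower, at an adjusted p under 0.05 and at least 2-fold. The split moved with scaling: 757 higher and 316 lower on unscaled signals, 571 and 609 with a common trimmed mean, and 494 and 734 with the bacterial hybridisation controls. Of the called genes of the naming rule, CXCL2, EGR3, HSPA4L, PSMD7 and SLC39A7 lost the call with a common trimmed mean, and these, BID and FKBP4 with the hybridisation controls. Of the 7 lists called, 4 were called without the first DMSO array and 3 without the second; the NRF2, immediate early and proteasome lists were lost in both cases and the p53 list in the second. Without the first elesclomol array the NRF2 list was lost. The authors' lists were chosen on these same arrays and are not independent evidence of a rise: of 1601 listed probe sets tested, 380 (23.7%) were called higher, all 1601 had a positive change and 1157 (72.3%) were at least 1.5-fold after scaling. A further 312 probe sets called higher were not listed. The falling probe sets stay unnamed. Of the rising probe sets without a name, the largest went from a signal of 7.55 ± 2.19 in DMSO to 2410 ± 294 after elesclomol (SD, n = 2 each). The next went from 32.2 ± 14.1 to 2597 ± 222, a rise of 6.30 (log2). It rose by 5.62 in the combination against paclitaxel. Their genes are not known here, so the largest rise in a gene list may be missing.

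The comparison of the combination with paclitaxel asked what elesclomol changed in the presence of paclitaxel, and it shared no array with the comparison on which the names rest. Of the genes tested, 16 of 27 heat shock chaperones, 5 of 7 metallothioneins, 6 of 13 NRF2 antioxidant genes and 5 of 13 integrated stress response genes rose. All but the heat shock list lost their call with an estimated correlation (adjusted p = 0.095, adjusted p = 0.146 and adjusted p = 0.15). Of all 1056 named genes 178 were called higher. HSPA6 had a signal of 6.75 ± 5.16 with paclitaxel and 4209 ± 193 with the combination (SD, n = 2 each), a rise of at least 350-fold. The 16 heat shock chaperone genes that rose were also 16 adjusted over the list alone, with a list median of 1.17: HSPA1B rose by 3.68, DNAJB1 by 2.90, DNAJB4 by 2.47 and BAG3 by 2.14, while AHSA1 had 0.95 and HSPE1 had 0.87. HSPA1A had 1.12, and 0.95 with a common trimmed mean. The heat shock list had an adjusted p = 1.32e-11, and an adjusted p = 0.00654 with an estimated correlation.

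Metallothioneins rose in 5 of 7 cases with paclitaxel present, also 5 adjusted over the list alone, with MT1F at 1.62, MT1E at 1.37 and MT1M at 1.22, and with MT2A at 0.63 under the limit. MT1X had 0.64, and passed with 1.44 in its other probe set. Without the first paclitaxel array 3 of 7 rose, as MT1G had 0.95 and MT1H 0.997. The list had an adjusted p = 0.00213, and an adjusted p = 0.095 with an estimated correlation. SLC30A1 rose by 2.27. NRF2 antioxidant genes rose in 6 of 13 cases, also 6 adjusted over the list alone: GCLM by 2.38, SLC7A11 by 2.21, TXNRD1 by 1.43 and SRXN1 by 1.36 (list adjusted p = 0.0116; adjusted p = 0.146 with an estimated correlation). Integrated stress response genes rose in 5 of 13 cases, also 5 adjusted over the list alone: SESN2 by 2.94, ATF3 by 2.00, TRIB3 by 1.45 and PPP1R15A by 1.18, while DDIT3 had 0.96, and passed with 1.35 on unscaled signals, 1.02 with a common trimmed mean and 1.22 with the hybridisation controls (list adjusted p = 0.0465; adjusted p = 0.15 with an estimated correlation). The list was not called without either paclitaxel array or without the first combination array.

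Of the 8 immediate early genes, 5 rose in the combination against paclitaxel, also 5 adjusted over the list alone, including IER5 by 2.32, NR4A1 by 2.23 and EGR1 by 2.05, but the list was not called (adjusted p = 0.0732). It passed on unscaled signals (adjusted p = 0.000925), on ranks (adjusted p = 0.0488) and without the first paclitaxel array. Of the 4 p53 targets, only SESN2 rose, which is also counted in the integrated stress response list. PMAIP1 at 0.89, GADD45A at 0.96 and CDKN1A at 0.59 stayed under the limit. The p53 list had an adjusted p = 0.0465, an adjusted p = 0.15 with an estimated correlation, and no call without the second paclitaxel or the first combination array. None of the 7 proteasome subunits reached the limit (limma), although their median was 0.85 and all 7 were above 0; the list had an adjusted p = 0.029, an adjusted p = 0.146 with an estimated correlation, and an adjusted p = 0.397 on unscaled signals. Of the ER chaperone list 4 of 12 genes rose, among them DNAJB9 by 1.41 (0.999 in another probe set) and HERPUD1 by 1.28. The list was not called (camera adjusted p = 0.282). The remaining lists were not called either, with an adjusted p of 0.756 for copper and zinc handling, 0.698 for apoptosis regulators, hypoxia and glycolysis genes and short-lived mRNAs, 0.738 for NF-kB and cytokine genes, and 0.267 for cholesterol synthesis. Of the other large named rises, ZFAND2A rose by 3.98 on the log2 scale, DUSP2 at least 18-fold and ARC at least 8-fold.

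**Figure D2:**
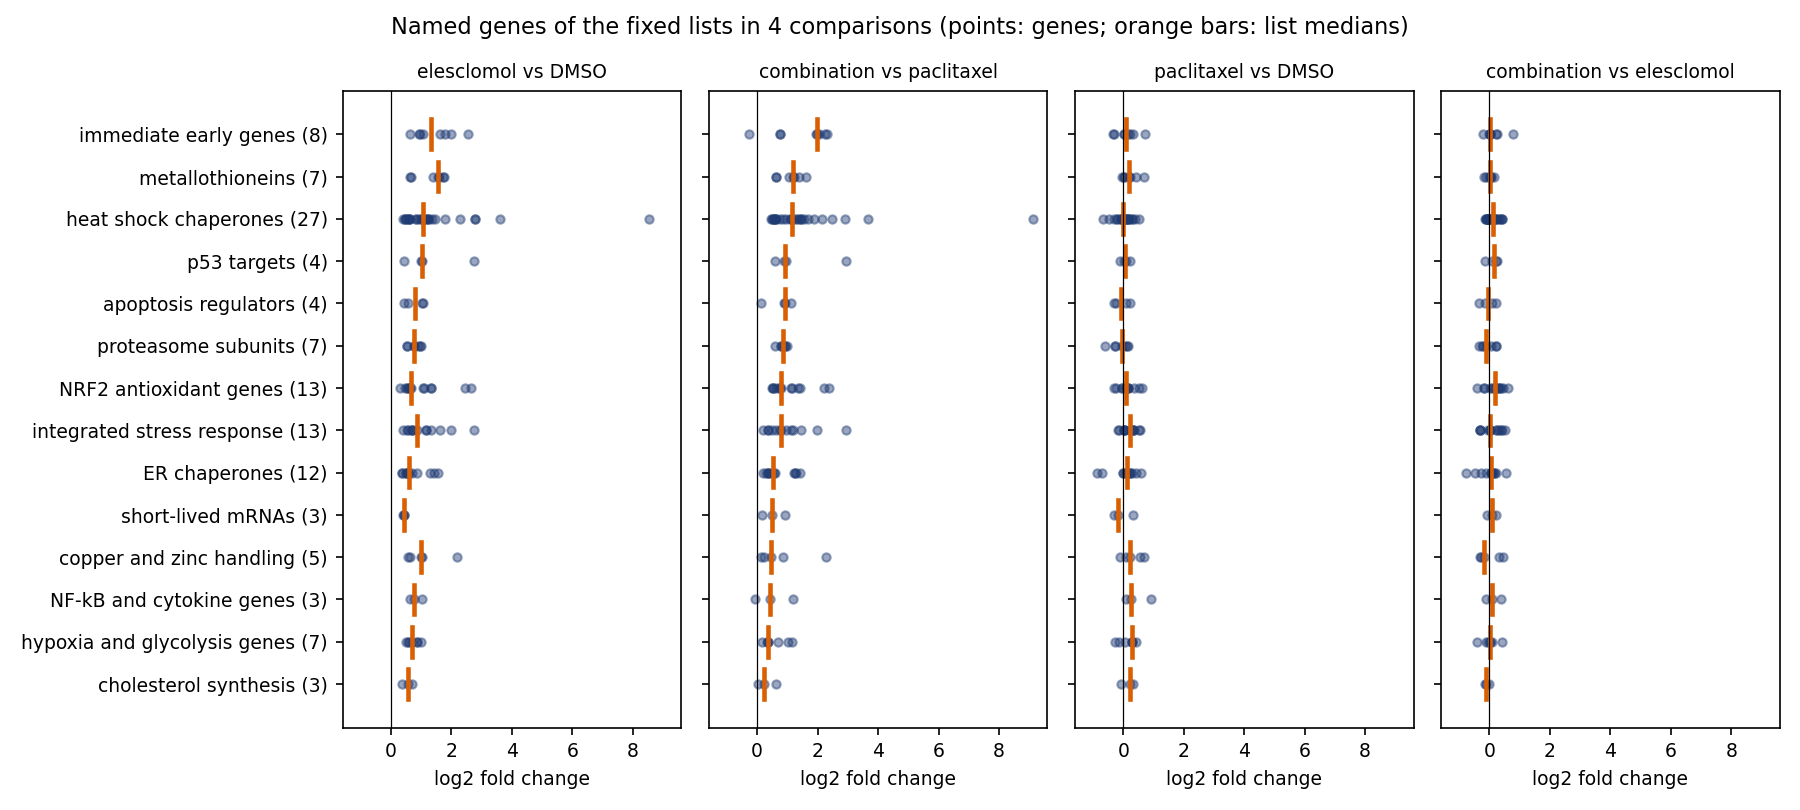
Log2 fold change of each named gene in the 14 tested lists in 4 comparisons; points are genes, orange bars are list medians and the number of genes is in brackets. Heat shock chaperones have a median of 1.05 for elesclomol against DMSO and 1.17 for the combination against paclitaxel, and of 0.00 for paclitaxel against DMSO and 0.11 for the combination against elesclomol.

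In total limma called 948 probe sets in the combination against paclitaxel, 630 higher and 318 lower. Unscaled signals gave 1447 higher and 102 lower, a common trimmed mean 582 and 483, and the hybridisation controls 1014 and 204. Of the 1601 listed probe sets, 1553 (97%) had a positive change here, 324 (20.2%) were called higher and 900 (56.2%) were at least 1.5-fold. The 5′ ends of actin and GAPDH, which track the length of the labelled RNA, stood apart in the combination: relative to the 3′ end and to DMSO, actin was at 0.408 and 0.356 and GAPDH at 0.381 and 0.429 (log2) on the 2 combination arrays, while on the paclitaxel arrays actin was at -0.083 and -0.084 and GAPDH at 0.06 and 0.133. The untreated arrays stood apart the other way, with actin at -0.451 and -0.38 and GAPDH at -0.295 and -0.236.

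The changes brought by elesclomol without and with paclitaxel were correlated across the 26589 probe sets (Pearson r = 0.567, Spearman rho = 0.545), and r was 0.889 across the 6543 probe sets with a mean signal of at least 100. Probe sets are not independent replicates, so no p is given. Of the probe sets called, 342 were higher in both comparisons, where independent lists would share 16.4, and 104 were lower in both, where independent lists would share 5.11. No probe set was called in opposite directions.

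**Figure D3:**
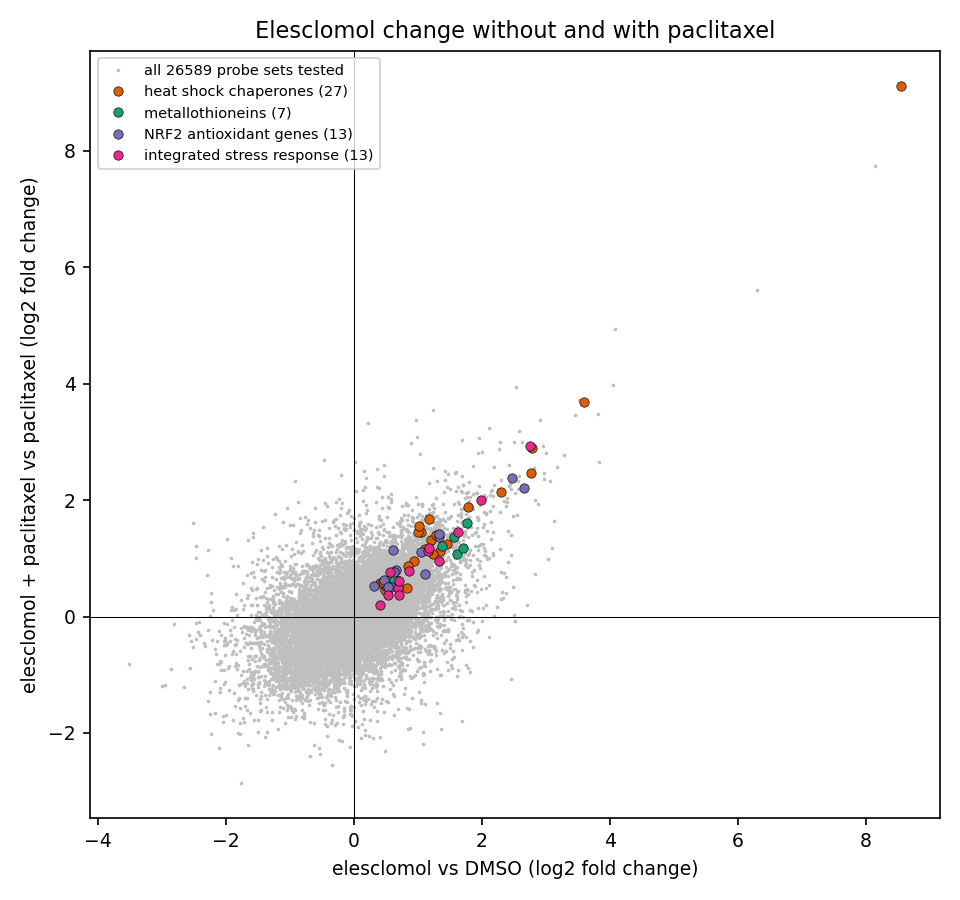
Log2 fold change of elesclomol against DMSO (x axis) and of the combination against paclitaxel (y axis) for the 26589 probe sets tested, with genes of 4 lists coloured. HSPA6 lies at fitted values of 8.55 and 9.12, from signals under 9 without elesclomol, and the coloured genes lie above 0 on both axes.

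The interaction asked whether the elesclomol change differed with and without paclitaxel. HSPA6 is given no difference, as its signal lay under 9 in both DMSO and paclitaxel. The difference was for DNAJB1 0.12 ± 0.09, for ATF3 0.01 ± 0.158 and for SLC30A1 0.08 ± 0.225 (log2, SE), each short of the limit. DDIT3 had -0.36 ± 0.132, HSPA1A -0.23 ± 0.063, MT1X -0.05 ± 0.087, MT2A 0.00 ± 0.071 and CDKN1A 0.15 ± 0.199. EGR1 had 1.09 ± 0.258 (adjusted p = 0.307, and an adjusted p = 0.00849 adjusted over the list alone); it was singled out after its values were seen, because it reached the limit only where paclitaxel was present. The named genes as a whole had a median of -0.12; they were selected for a high elesclomol value against DMSO, which biases this difference downward. Heat shock chaperones had a median of 0.06 and lay above the other named genes (camera adjusted p = 0.00345; adjusted p = 0.129 with an estimated correlation). Set against all probe sets, which were not so selected, the list was not called (adjusted p = 0.155). With a common trimmed mean, or without the second paclitaxel array, no list was called. None of the other 13 lists was called, with adjusted p between 0.176 and 0.99. limma called 0 probe sets at the 2-fold limit, while 2054 had an unadjusted p under 0.05 and 3 an adjusted p under 0.05. Without the first or the second DMSO array the count was 1 in each case, unscaled signals gave 1, and the hybridisation controls gave 12. In simulated data an interaction of log2 1.5 was called in 24% of the 50 probe sets given one, and one of log2 3 in 74% of 50.

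The comparison of the combination with DMSO gave the joint effect of both drugs. The 5′ ends of actin and GAPDH were raised on both combination arrays, as given above relative to DMSO. The poly-A labelling controls were at 12.6% and 12.37% of the hybridisation controls on the combination arrays and 17.79% and 19.46% on the DMSO arrays. HSPA6 rose at least 367-fold and DUSP2 at least 17.4-fold, and on the log2 scale ZFAND2A rose by 3.94 and HSPA1B by 3.77. Of the heat shock chaperones 17 of 27 rose, of the metallothioneins 5 of 7 and of the NRF2 antioxidant genes 6 of 13. Of the integrated stress response genes 9 of 13 rose, of the immediate early genes 6 of 8 and of the ER chaperone list 3 of 12. Each count was the same adjusted over the list alone. Of all 1056 named genes 251 were called higher, a share near that of the ER chaperone list. The names rest on the same DMSO arrays, which biases this comparison upward for named genes and their lists. GCLM rose by 2.92, SLC7A11 by 2.82, SESN2 by 2.96, ATF3 by 2.02 and SLC30A1 by 2.50. MT2A at 0.64 and CDKN1A at 0.70 stayed under the limit, although CDKN1A passed with 1.07 on unscaled signals. MT1X had 0.66, and passed with 1.66 in its other probe set. DDIT3 passed at 1.01, but had 0.96 without the first DMSO array and 0.98 without the second combination array. ARC rose at least 8-fold, EID3 by 3.18, DNAJB1 by 2.90, DNAJB4 by 2.62 and IER5 by 2.53.

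The 4 lists called in the combination against DMSO were heat shock chaperones (adjusted p = 2.35e-10; adjusted p = 0.00866 with an estimated correlation), metallothioneins (0.000647; adjusted p = 0.0694 with an estimated correlation), NRF2 antioxidant genes (0.0156; adjusted p = 0.131 with an estimated correlation) and the integrated stress response (0.023; adjusted p = 0.131 with an estimated correlation). Immediate early genes and p53 targets each had an adjusted p = 0.0511. On unscaled signals these lists had an adjusted p = 0.000856 and an adjusted p = 0.00952. The immediate early list was also called on leaving out any 1 array, and the p53 list without the first DMSO or the second combination array. limma called 1673 probe sets, 974 higher and 699 lower. Unscaled signals gave 2038 higher and 269 lower, a common trimmed mean 812 and 935, and the hybridisation controls 1424 and 477. Of the called genes of the naming rule, NDRG1 lost the call with a common trimmed mean.

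The comparison of paclitaxel with DMSO asked what paclitaxel alone changed by 6 h. Of the 1056 named genes only 9 were called, a share at which lists of these sizes would mostly hold none. Heat shock chaperones had a median of 0.00, metallothioneins 0.18 and NRF2 antioxidant genes 0.10, with 0 members called in any of the 14 lists. HSPA6 lay under 9 in both groups. DNAJB1 had 0.00 ± 0.064, ATF3 0.02 ± 0.112, SLC30A1 0.23 ± 0.159, HSPA1A 0.15, MT1X 0.02, MT2A 0.02, DDIT3 0.05 and CDKN1A 0.10. The 6 largest named rises were LRRFIP1 by 1.38, NCKAP1, a subunit of the WAVE actin regulator, by 1.31, LCORL by 1.14, SOAT1, which esterifies cholesterol, by 1.13, CD164 by 1.09 and ASAH1, the acid ceramidase, by 1.07. NCKAP1 had signals of 132 ± 14.1 in DMSO and 323 ± 18.6 after paclitaxel (SD, n = 2 each).

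These 6 genes were called in the comparison with DMSO only where limma modelled the spread as a trend in intensity. Without the trend their log2 rises were the same, and their adjusted p lay between 0.171 (NCKAP1) and 0.222 (LCORL). On unscaled signals LRRFIP1 (adjusted p = 0.008) and NCKAP1 (0.00664) passed and the other 4 had 0.118 to 0.184. LRRFIP1 and NCKAP1 passed without each array in turn. LCORL and SOAT1 did not pass without any of the 4 arrays (adjusted p of 0.0566 to 0.237 and 0.0658 to 0.122). CD164 failed without the first DMSO array (0.06) and without either paclitaxel array (0.0563 and 0.0647), and ASAH1 without the second DMSO array (0.0641) and without either paclitaxel array (0.0763 and 0.0667). The genes had also been selected as raised by elesclomol against the same DMSO arrays, which biases this comparison upward. limma called 85 probe sets, 52 higher and 33 lower, against 10 higher and 8 lower on unscaled signals and 6 in all without the trend. Most of the 85 calls were lost without the first DMSO array, and also without either paclitaxel array, and some other probe sets were called instead. Camera called no list, with adjusted p between 0.563 and 0.994, and fry, which asks only whether a list moves on balance in 1 direction, called 5.

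Paclitaxel binds tubulin in microtubules and blocks mitosis. The lists of tubulin genes and of G2/M and mitosis genes had no named member, nor had the melanocyte lineage, fibroblast, leukocyte and keratinocyte markers. These lists gave no result in any comparison.

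The comparison of the combination with elesclomol asked what paclitaxel changed in the presence of elesclomol. The 5′ ends of actin, at -0.167 and -0.168 on the elesclomol arrays, and of GAPDH, at -0.036 and -0.157, lay below those on the combination arrays given above. None of the 1056 named genes was called by limma in its brightest probe set, while 4336 probe sets had an unadjusted p under 0.05; other probe sets of GCLM and PSAP were called (1.03 and 1.23). HSPA6 had 0.12 ± 0.38, DNAJB1 0.12 ± 0.064, HSPA1A -0.08, MT1X -0.03, MT2A 0.02, SLC30A1 0.31, ATF3 0.03, DDIT3 -0.32 and CDKN1A 0.25. Heat shock chaperones had a median of 0.11 and NRF2 antioxidant genes of 0.20, each with an adjusted p = 0.0604, and no list was called. With the replicate number as a block 2 lists were called, and with the hybridisation controls 1. limma called 59 probe sets, 31 higher and 28 lower, against 68 and 4 on unscaled signals, 305 and 27 with the hybridisation controls, and 0 without the trend in intensity. Most of the 59 calls were lost on leaving out any 1 of the elesclomol or combination arrays, and other probe sets were called in their place. The paclitaxel changes without and with elesclomol had r = 0.236 (rho = 0.293) over all probe sets and r = 0.597 over the 6543 with a mean signal of at least 100. They shared 2 calls higher, where independent lists would share 0.06, and 0 lower.

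The direct comparison of the single drugs used the same elesclomol arrays as the comparison of elesclomol with DMSO, so likeness between them is no independent evidence. HSPA6 was higher with elesclomol than with paclitaxel by at least 322-fold, DUSP2 by at least 7.93-fold and ARC by at least 7.97-fold. On the log2 scale ZFAND2A was higher by 4.10, HSPA1B by 3.51, DNAJB1 by 2.79, ATF3 by 1.97, SLC30A1 by 1.96, DDIT3 by 1.28 and HSPA1A by 1.20. MT2A at 0.61 and CDKN1A at 0.34 stayed under the limit, and MT1X had 0.66 but passed in its other probe set. Of all 1056 named genes 217 were called higher with elesclomol. The names rest on the same elesclomol arrays, which biases this comparison upward for named genes. Heat shock chaperones (14 of 27 higher, also 14 adjusted over the list alone; list adjusted p = 2.97e-08; adjusted p = 0.015 with an estimated correlation) and metallothioneins (5 of 7, also 5 adjusted over the list alone; 0.00509; adjusted p = 0.122 with an estimated correlation) were called. Proteasome subunits had 4 of 7 higher, also 4 adjusted over the list alone (list adjusted p = 0.0594; adjusted p = 0.0421 on ranks and adjusted p = 0.286 on unscaled signals), and the list was called without the first elesclomol array. Of these 4, PSMD7 had 0.97 with a common trimmed mean and 0.92 with the hybridisation controls, PSMD12 had 0.83 in its other probe set, and PSMC6 had 0.95 without the first elesclomol array and 0.999 without the first paclitaxel array. On unscaled signals the p53 list (adjusted p = 0.0398) and the immediate early list (adjusted p = 0.00814) passed, against an adjusted p = 0.223 each. limma called 1146 probe sets, 721 higher and 425 lower with elesclomol. Unscaled signals gave 823 and 309, a common trimmed mean gave 618 and 620, and the hybridisation controls 535 and 782.

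The elesclomol and paclitaxel changes share the DMSO arrays, so part of their correlation comes from chance. Their r was 0.372 with a covariance of 0.0929. Simulated unchanged groups, set against a simulated DMSO group that they shared, gave a mean r of 0.498 and a mean covariance of 0.0682. With a separate DMSO array for each drug, a setting chosen after seeing the data, r was 0.055 and 0.06, against a noisier single control. The comparisons shared 23 calls higher and 1 lower; how many the shared arrays alone would give was not simulated.

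The comparison of DMSO at 6 h with untreated cells at 0 h covered the vehicle and 6 h of culture together. No named gene was called: HSPA6 lay under 9 in both groups, DNAJB1 had 0.12 ± 0.064, HSPA1A -0.08, MT1X 0.10, MT2A 0.11, SLC30A1 -0.05, ATF3 -0.13, DDIT3 0.00 and CDKN1A -0.12. The 14 lists had camera adjusted p of 0.882 to 0.926, and the hypoxia and glycolysis list had the lowest median at -0.22. The names rest on the same DMSO arrays, which biases this comparison downward for named genes. The 5′ signals of actin and GAPDH also differed between the groups, being lower relative to the 3′ end on both untreated arrays. limma called 0 probe sets, with 2324 at an unadjusted p under 0.05 and 1 at an adjusted p under 0.05. Leaving out the first untreated array gave 18, the second 16 and the second DMSO array 4. On unscaled signals 6 were called, and after scaling to the hybridisation controls 1175 were higher and 15 lower, with a median change of 0.50 over all probe sets; HSPA6 was then among the calls, although under 9 in both groups.

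**Figure D4:**
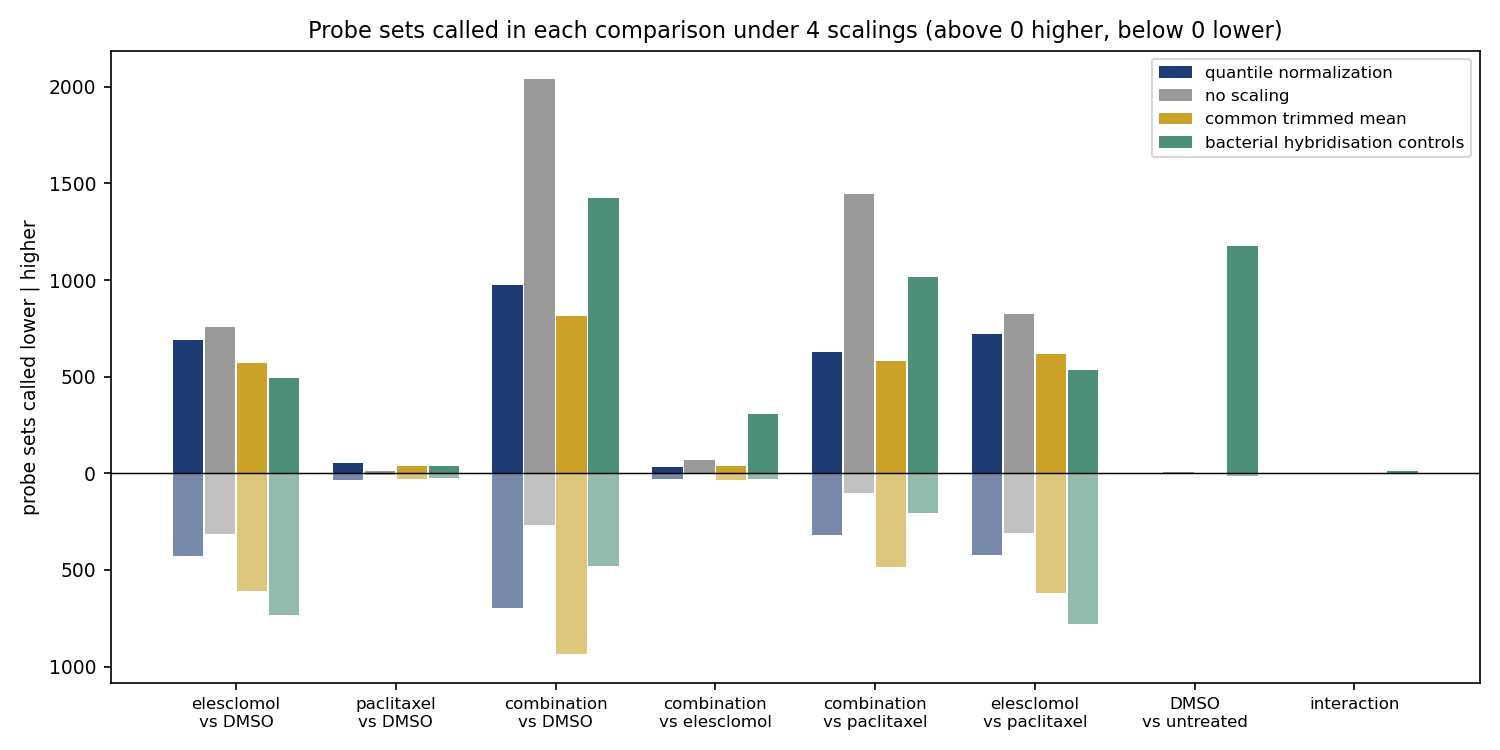
Number of probe sets called higher (above 0) and lower (below 0) in the 8 comparisons under 4 ways of scaling the arrays; each bar is a count of probe sets. In the combination against DMSO 974 were higher and 699 lower after quantile normalization, and 2038 and 269 without scaling.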

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

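These results stood out in tests of a difference between effects, or in control probe sets that no comparison used. The look at the other TNPO1 probe sets was chosen after its values were seen.

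The nuclear import receptor TNPO1 had an interaction of -0.911 ± 0.111 (log2, SE; limma adjusted p = 0.0443): elesclomol changed it by 1.10 without paclitaxel and by 0.19 with it. The 6 other TNPO1 probe sets tested had interactions from -0.27 to 0.34, with adjusted p of at least 0.602. A pair of unnamed probe sets had interactions of 0.627 (-0.077 without and 0.55 with paclitaxel) and 0.687 (0.046 and 0.734), each with an adjusted p = 0.0443. All 3 were under the 2-fold limit. The heat shock chaperones lay above the other named genes in the interaction with a camera adjusted p = 0.00345, against an adjusted p = 0.129 with an estimated correlation. The named genes are biased downward in this difference by their selection. Set against all probe sets the list was not called (camera adjusted p = 0.155), nor was it with a common trimmed mean.

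The 3 control probe sets for 18S ribosomal RNA were brighter in the combination than in DMSO, by 3.4, 4.93 and 5.55-fold on the deposited signals. Their signals were 40.3 ± 5.8, 122 ± 28.3 and 171 ± 3.89 in the combination and 11.8 ± 3.18, 24.8 ± 5.16 and 30.8 ± 4.6 in DMSO (SD, n = 2). After quantile normalization the folds were 2.76, 4.01 and 4.4. Elesclomol stood at 1.79, 2.12 and 3.28 times DMSO, paclitaxel at 1.13, 1.58 and 1.39 and untreated cells at 2.14, 2.59 and 2.57. The differences were not tested across groups, and no explanation of them was tested.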

How the results depend on the processing

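The scalings to a common trimmed mean and to the hybridisation controls, and the lists set against all probe sets, were chosen after seeing the data. Over all settings 91 probe set counts stayed within 1.5 times the reported count and 57 moved further, as did 114 and 26 counts of lists. Of the values of named genes, 4638 kept their side of the threshold, 32 newly passed and 134 no longer passed (70 of these on leaving out 1 array, 22 in another probe set), and 0 reversed. The correlations of the elesclomol changes and of the paclitaxel changes were higher with the stricter filter, and that against the shared DMSO was lower. Fits with 1 probe set per gene or with the mean over a gene's probe sets were not run. Where a setting relaxes or tightens a threshold or the filter, its construction moves the count; otherwise the cause was not tested.

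An adjusted p under 0.01 left 19 calls in paclitaxel against DMSO, 15 in the combination against elesclomol and 748 in elesclomol against paclitaxel. A 1.5-fold limit gave 2835 (elesclomol against DMSO), 298 (paclitaxel against DMSO), 4129 (combination against DMSO), 357 (combination against elesclomol), 2686 (combination against paclitaxel), 2957 (elesclomol against paclitaxel), 3 (interaction) and 1 (DMSO against untreated), and 1078 of the authors' listed probe sets. With no fold limit these were 4584, 704, 6225, 985, 4394, 4766, 3 and 1, and 1461. Without a test, with every array at least 2-fold apart, elesclomol against DMSO had 649, paclitaxel against DMSO 141, the combination against DMSO 957, the combination against elesclomol 115, elesclomol against paclitaxel 678 and DMSO against untreated 110, with 222 of the listed probe sets. The authors' thresholds, with SD over mean under 0.4 in place of their SE and applied in both directions, gave 2490 in elesclomol against DMSO, 1720 higher and 770 lower.

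A filter at the 75th percentile gave 620, 42, 972, 22, 579 and 624 in the first 6 comparisons, in the order given for the 1.5-fold limit, and 1 in the interaction, with 4 lists in elesclomol against DMSO. No filter gave 55 in paclitaxel against DMSO and 35 in the combination against elesclomol. Unscaled signals, as planned at first, gave 18 in paclitaxel against DMSO, 1549 in the combination against paclitaxel, 1 in the interaction and 6 in DMSO against untreated, with 4 lists in elesclomol against paclitaxel. The hybridisation controls gave 332 in the combination against elesclomol, with 1 list, 12 in the interaction and 1190 in DMSO against untreated. A common trimmed mean left 0 lists in the interaction. Without the intensity trend limma called 6 in paclitaxel against DMSO and 0 in the combination against elesclomol, where 4336 had an unadjusted p under 0.05 with the trend. Fitting only the arrays of the groups compared gave 2 in the interaction.

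The correlation of the elesclomol changes (r = 0.567) was 0.545 by Spearman, 0.615 with 4 times the pseudocount, 0.203 with no filter and 0.817 with the 75th percentile filter. That of the paclitaxel changes (0.236) was 0.293, 0.269, 0.078 and 0.469. That against the shared DMSO (0.372) was 0.454 with no filter and 0.296 with the stricter one. With a separate DMSO array for each drug, chosen after seeing the data, it was 0.055 and 0.06.

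Camera on ranks called 2 lists in elesclomol against DMSO and 2 in the combination against DMSO. With an estimated correlation 2 and 1 were called, with 1 in the combination against paclitaxel, 1 in elesclomol against paclitaxel and 0 in the interaction. Fry called 14 of 14 in elesclomol against DMSO, the combination against DMSO, the combination against paclitaxel and elesclomol against paclitaxel, 5 in paclitaxel against DMSO and 0 in the interaction. Against all probe sets the lists called were 14, 14, 13, 14 and 2 in the first 5 of these; the named genes were listed as raised, so this sets raised genes against the rest.

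Leaving out each array in turn, with the lone array of a group assumed to vary like the other groups, gave 23 to 76 calls in paclitaxel against DMSO, 31 to 120 in the combination against elesclomol, 0 to 18 in DMSO against untreated and 0 to 1 in the interaction. Lists called ran from 3 to 7 in elesclomol against DMSO and from 0 to 1 in the interaction. The correlations ran from 0.504 to 0.539, from 0.193 to 0.225 and from 0.32 to 0.548. The calls in elesclomol against DMSO ran from 932 to 1184, in the combination against DMSO from 1343 to 1816, in the combination against paclitaxel from 790 to 860 and in elesclomol against paclitaxel from 917 to 1141.

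With the replicate number as a replicate block, 2 lists were called in the combination against elesclomol, where 0 were called without it; the cause was not tested. The block moved no count of probe sets by over 1.5 times. Arrays of the same number share only a number: their deviations correlated between -0.25 and 0.261 over the pairs of groups.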

Other observations

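All tests of explanations below were chosen after the result was seen.

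Of the lists too small to test, 1 named gene was called. The ribosomal protein RPL37 rose by 1.35 ± 0.254 in elesclomol against DMSO (adjusted p = 0.0027), 1.33 in the combination against DMSO and 1.16 in the combination against paclitaxel (log2, SE); the last was not called without the first paclitaxel array or the second combination array. FTL, the light chain of the iron store ferritin, had 0.46, 0.77 and 0.62, under the 2-fold limit in each. SDHD, a subunit of respiratory complex II, had 0.56 ± 0.102 in paclitaxel against DMSO and 0.91 in the combination against DMSO, also under that limit. All are genes the authors listed as raised by elesclomol.

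The paclitaxel and combination arrays differed from the DMSO and elesclomol arrays in the same probe sets (r = 0.597 over 6543 with a mean signal of at least 100). The difference between the 2 untreated arrays, which received no drug, correlated with paclitaxel against DMSO at 0.354, where the other within-group differences reached 0.179 at most, so a preparation difference between arrays may contribute. Whether it is the whole cause cannot be told apart: its correlation with the combination against elesclomol was 0.121, where 1 shared direction requires 0.212, but only 12 of 16 single-array pairings lay below. The poly-A labelling controls relative to the hybridisation controls were lower on all 4 arrays with paclitaxel than on all 4 DMSO and elesclomol arrays, by a gap of 0.115 (log2), and were as low on the untreated arrays (13.23% and 11.2%, against 12.37% to 15.93% with paclitaxel), so a difference in the labelling reactions may also contribute. An effect of paclitaxel itself stays open.

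Without scaling, the calls of the combination against DMSO lay mostly on the higher side. Array brightness is a candidate explanation: scaling to the hybridisation controls, which does not centre the arrays, lowered the share of higher calls by 13.4 percentage points, from 88.3% to 74.9%, a test and limits chosen after seeing the data. The median change of all probe sets was then still 0.118 (log2), above the largest shift of 0.072 in size between arrays of 1 group. The hybridisation controls do not pass through the labelling reaction. This shift therefore cannot show whether message per unit of total RNA changed, which stays open. On this scale elesclomol against DMSO lay at -0.131 and DMSO against untreated cells at 0.503, so shifts of this size between groups were not limited to the combination. A labelling difference, with the poly-A controls at 12.6% and 12.37% of the hybridisation controls on the combination arrays and 17.79% and 19.46% on the DMSO arrays, stays open, as do the raised 5′ signals of actin and GAPDH.

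The authors marked some of the genes they annotated for HSF-1, the main regulator of the heat shock response. In the combination against paclitaxel, whose arrays the lists did not use, the 20 marked genes had a median of 1.405 and 16 were called, and the 104 other annotated genes had a median of 1.18 and 59 called. Draws of other annotated genes matched on signal reached 1.22 at their upper 95% bound and 1.419 at the highest of 10000, which argues against brightness alone. The 8 marked genes outside the heat shock list had a median of 1.22, and the 12 inside it 1.66. Draws for the 8, which were not matched on signal, had a middle 95% of 0.803 to 1.849. Whether only the chaperones carry the difference cannot be told apart with 8 genes, and regulation by HSF-1 may contribute but was not measured.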
